A study of Anopheles merus and Anopheles coluzzii with 36 samples.

How the data were processed

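The samples were 36 libraries of pooled whole larvae, 18 each of An. merus and An. coluzzii, in 12 groups of 3 by species and salinity. Per the labels, RNA was selected for poly(A) and libraries were made with a TruSeq kit. Per the submitters' processing notes, Trimmomatic, Bowtie2, TopHat2, HTSeq and edgeR were used. Their versions, the genome build, the annotation and the threshold of the filter on low genes are not given in the sources used here.

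The deposited table holds 1 normalized expression signal per gene and library for 10905 genes, which the authors gave as CPM (reads scaled to a common library size) with TMM scaling (trimmed mean of M values), filtered and without ribosomal RNA, per the file's name. TMM assumes that most genes do not change between libraries, so the column sums differ between libraries (891810 to 1215180) and changes are relative to the bulk of genes. Each value was a whole multiple of the worth of 1 read, within 0.001, for 100% of the values in every library, and these multiples were taken as the reads. Every gene had at least 1 CPM, before TMM, in at least 3 libraries. The An. coluzzii library C at 50% was sequenced in 5 lane parts per the labels, and its column is named for 1 of them; whether it holds 1 part or all is not given in the sources used here. It held 15369828 reads, the fewest of that species. In single libraries 71 to 138 genes had no read in An. merus and 23 to 41 in An. coluzzii. A count of 0 allows up to 3 reads, which equal 0.114 to 0.348 CPM depending on the library, and covers counting error only.

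Values were tested as log2(CPM + 0.5), with no further filter, in limma 3.58.1 (R 4.3.3): 1 model with 12 group means over all 36 libraries, moderated by empirical Bayes with a mean trend, two-sided, with Benjamini-Hochberg adjustment over 10905 genes within each comparison and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. Comparisons were each salinity against 0% within a species, a linear trend over salinity within a species, the species at 0%, and the interaction of species and salinity at 50% and, by an F test, over all salinities. These tests, the rule for named genes and most alternatives were fixed before the data were examined. The interaction at single salinities from 10 to 40%, the opposite calls, the correlations between species and the change from 40 to 50% were added afterwards. Tests were unpaired.

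Of 16199 genes in the reference table at hand, which holds An. merus genes, 0 matched the identifiers of the deposited table. No gene names or coordinates could therefore be given, and the lists of ion transport, cuticle, stress and other genes fixed in advance were not tested. With no names, the rule named for 50% against 0% in each species, for the species at 0% and for the interaction at 50% the 2 genes risen most and the 2 fallen most, among those past the threshold with a mean of at least 5 CPM in the groups compared and, except for the interaction, no overlap between groups. The genes that met these conditions numbered 5869, 5648, 3071 and 5123.

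The procedure was tested on simulated reads for 10905 genes with known fold changes, of 1.5-fold in 67, 2-fold in 67 and 4-fold in 66 of them. For An. merus at 50% it recovered 49.3% of the changes of 1.5-fold, 91.0% of 2-fold and 98.5% of 4-fold, for An. coluzzii at 50% 38.8, 86.6 and 97.0%, and for the species at 0% 49.3, 85.1 and 93.9%. For the interaction at 50% it recovered 5.97, 56.7 and 89.4%, so in the simulation small differences in response were often missed. False calls among the unchanged genes numbered 5, 11, 3 and 11 in the same order. The cutoff of the adjustment depends on how many genes change, and far more genes were called in the data than were changed here. The simulation also gave all groups the same spread per gene and both species the same mean profile apart from the changes set. In the data the pools at 0% stood further apart (below). The shares and the numbers of false calls therefore need not hold for the data.

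Alternatives were a pseudocount of 0.1 or 2, a filter at a mean of 5 CPM, quantile normalization, the replicate letter as a block, robust variances, each species alone, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, each library left out in turn, a slope over 0 to 40%, the species averaged over 6 salinities and, added after the data were seen, scaling by library totals. On the recovered reads edgeR called 7440 genes in An. merus and 7466 in An. coluzzii at 50%, and 5782 for the interaction at 50%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.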

Results

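Gene expression was measured by poly(A) RNA sequencing in newly hatched larvae of 2 sibling malaria vectors. Anopheles merus is euryhaline, meaning that its larvae tolerate a wide range of salt concentrations. Anopheles coluzzii is stenohaline and develops in fresh water. Larvae of both species were raised in fresh water until 18 h after hatching and then held for 6 h in water of 0, 10, 20, 30, 40 or 50% of the salinity of seawater. Each library came from a pool of whole larvae, and each of the 12 combinations of species and salinity had 3 libraries, 36 in all. The labels do not say whether the pools of a group came from separate cultures, so p-values cover only the spread between pools. That spread was estimated per gene over all 12 groups together. Pools at 0% stood further apart within their groups, on average, than those at other salinities (below). The p-values and counts of comparisons that use the 0% libraries may therefore be too favourable. Libraries held 9174563 to 24092192 counted reads in An. merus and 15369828 to 24835904 in An. coluzzii, over 10905 genes. Replicates of a group differed by more than sampling noise in all 36 pairs, so none was a duplicate of another. The gene identifiers are those of the deposited table, which pairs them with no names, so genes are given by identifier.

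The first principal component, with 44.3% of the variance of the log2 values, separated the species, and salinity moved both species along the first 2 components. In An. merus the mean score on the second component (22.4% of the variance) was 6.54 ± 7.41 at 0% and -52.5 ± 5.38 at 50% (SD, n = 3). In An. coluzzii it was 44.4 ± 5.75 at 0%, 5.70 ± 3.98 at 30% and -26.4 ± 3.20 at 50% (SD, n = 3). The An. coluzzii libraries at 40 and 50% lay together on these components and apart on the third (12.7% of the variance), with mean scores of 1.27 ± 8.50 and 45.9 ± 0.844 (SD, n = 3).

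**Figure D1:**
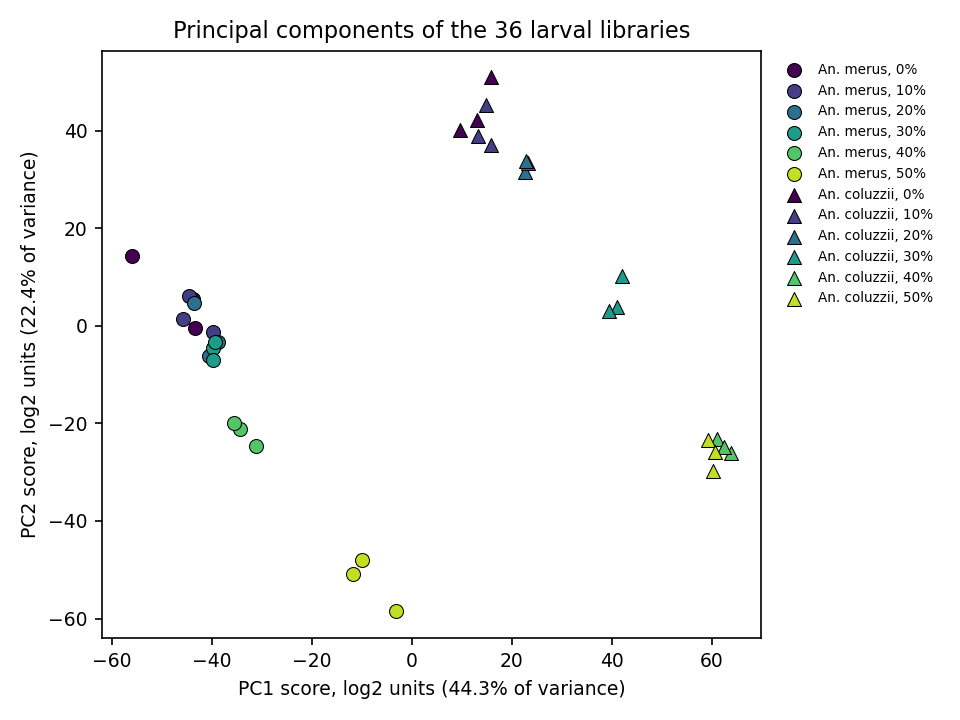
Scores of the 36 libraries on the first 2 principal components of log2(CPM + 0.5), in log2 units, with circles for An. merus, triangles for An. coluzzii and colour for salinity. An. merus libraries lie left of the An. coluzzii libraries on the first component, which holds 44.3% of the variance, and both species move down the second component at high salinity.

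The response of An. merus to salinity was asked by comparing each salinity with 0%. AGAP009460 rose from 1.45 ± 1.0 CPM at 0% to 107 ± 34.9 CPM at 50% (SD, n = 3), a log2 fold change of 5.85 ± 0.31 (SE; limma adjusted p = 8.4e-15), and stood at 4.19 ± 0.575 CPM at 40%. AGAP000239 rose from 3.09 ± 2.05 to 145 ± 33.1 CPM (SD, n = 3; log2 fold change 5.45 ± 0.80 SE, limma adjusted p = 8.5e-07). AGAP009591 fell from 254 ± 38.4 to 11.2 ± 7.56 CPM (SD, n = 3; log2 fold change -4.61 ± 0.61 SE, limma adjusted p = 1.6e-07), and AGAP002798 from 454 ± 186 to 28.1 ± 3.79 CPM (SD, n = 3; log2 fold change -3.91 ± 0.34 SE, limma adjusted p = 1.0e-10).

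Over all genes, the number that differed from 0% in An. merus grew with each step of salinity. It was 87 at 10% (24 higher, 63 lower), 1283 at 20% (514 higher, 769 lower), 2112 at 30% (948 higher, 1164 lower), 4286 at 40% (1937 higher, 2349 lower) and 7594 at 50% (3482 higher, 4112 lower), by limma at an adjusted p under 0.05. Changes of at least 2-fold were made by 30, 115, 217, 621 and 2615 of them. The counts at low salinity depended on single libraries. At 10% the count was 41, 144 and 415 without replicates A, B and C at 0% (250 higher and 165 lower without C), and 32 and 36 without replicates A and B at 10%. At 20% it was 270, 2040 and 2193 without replicates A, B and C at 0% (1034 higher and 1006 lower without B), 650 and 299 without replicates A and B at 20%, and 557 with the species fitted alone. At 10% it was 52 with the species fitted alone and 141 with DESeq2. At 30% it was 874 without replicate A at 0% and 1290 without replicate A at 30%.

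The same comparisons in An. coluzzii called 6 genes at 10% and 5473 at 30%. AGAP004581 rose from 1.06 ± 0.929 CPM at 0% to 119 ± 36.3 CPM at 50% (SD, n = 3; log2 fold change 6.38 ± 0.48 SE, limma adjusted p = 4.9e-12). AGAP004583 rose from 0.993 ± 0.585 to 89.4 ± 27.0 CPM (SD, n = 3; log2 fold change 5.94 ± 0.49 SE, limma adjusted p = 2.5e-11). Both also rose in An. merus at 50%, by 5.26 ± 0.48 and 5.36 ± 0.49 on the log2 scale (SE). AGAP004130 fell from 517 ± 679 to 0.357 ± 0.396 CPM (SD, n = 3; log2 fold change -8.39 ± 1.45 SE, limma adjusted p = 1.2e-05), and AGAP004131 from 910.4 ± 1255 to 2.96 ± 2.60 CPM (SD, n = 3; log2 fold change -7.23 ± 1.27 SE, limma adjusted p = 1.5e-05). The 0% libraries were far apart for this second pair, from 95.2 to 1300.3 CPM for AGAP004130. Across libraries with at least 20 reads of both genes, log2 reads of AGAP004581 and AGAP004583 correlated at 0.998 (26 libraries) and those of AGAP004130 and AGAP004131 at 0.956 (28 libraries). Whether reads were shared between similar copies was not tested, so each pair is uncertain as 2 separate measurements.

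At 10%, 6 genes differed from 0% in An. coluzzii (5 higher, 1 lower). AGAP006968 rose from 2.27 ± 0.173 to 7.89 ± 1.21 CPM (SD, n = 3; limma adjusted p = 0.0019), AGAP006442 rose from 1.10 ± 0.109 to 2.81 ± 0.889 CPM (limma adjusted p = 0.038) and AGAP010508 fell from 7.77 ± 1.70 to 3.70 ± 0.412 CPM (limma adjusted p = 0.0057), all 3 chosen for naming after their values were seen. AGAP006442 lost its call with a pseudocount of 2, under the replicate block and with the species fitted alone, and AGAP010508 with the species fitted alone. Of 6 fits that each left out a library, AGAP006442 lost its call in 5 and AGAP010508 in 2 (without replicate A at 0% or C at 10%). The counts were 1673 at 20% (819 higher, 854 lower), 5473 at 30% (2526 higher, 2947 lower), 7154 at 40% (3335 higher, 3819 lower) and 7417 at 50% (3454 higher, 3963 lower), with 141, 1052, 2121 and 2429 of at least 2-fold. At 10% the count was 1 without replicate A at 0%, 3 without replicate A or B at 10%, and 1 without replicate C at 10%. It was 2 under the replicate block, 1 with the species fitted alone and 17 with DESeq2 (7 higher, 10 lower). At 20% it was 551 without replicate A at 0%, 832 without replicate A at 20% and 1021 without replicate C at 20%.

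The 100 most abundant genes took a growing share of the reads in An. coluzzii, 34.9 ± 0.168% at 0%, 38.3 ± 1.13% at 30%, 41.2 ± 0.149% at 40% and 43.4 ± 1.63% at 50% (SD, n = 3). In An. merus the share was 35.2 ± 2.03% at 0% and 36.8 ± 1.17% at 50% (SD, n = 3). The division of calls into higher and lower depends on how the libraries are scaled. With library totals in place of the deposited TMM scaling, the median log2 change of all genes moved by -0.16, -0.28 and -0.28 in An. coluzzii at 30, 40 and 50% and by -0.13 in An. merus at 50%, and the directions reported are relative to these shifts. With that scaling, higher and lower genes numbered 5 and 2 in An. coluzzii at 10% (7 and 10 with DESeq2), 624 and 1132 at 20%, 1591 and 3948 at 30%, 1905 and 5297 at 40%, and 2189 and 5456 at 50%. In An. merus they were 33 and 75 at 10%, 462 and 553 at 20%, 888 and 1031 at 30%, 1878 and 2169 at 40%, and 2800 and 4685 at 50%. With quantile normalization more genes were higher than lower in An. merus at 40% (2198 and 2098) and in An. coluzzii at 20% (983 and 850) and 50% (3667 and 3556).

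**Figure D2:**
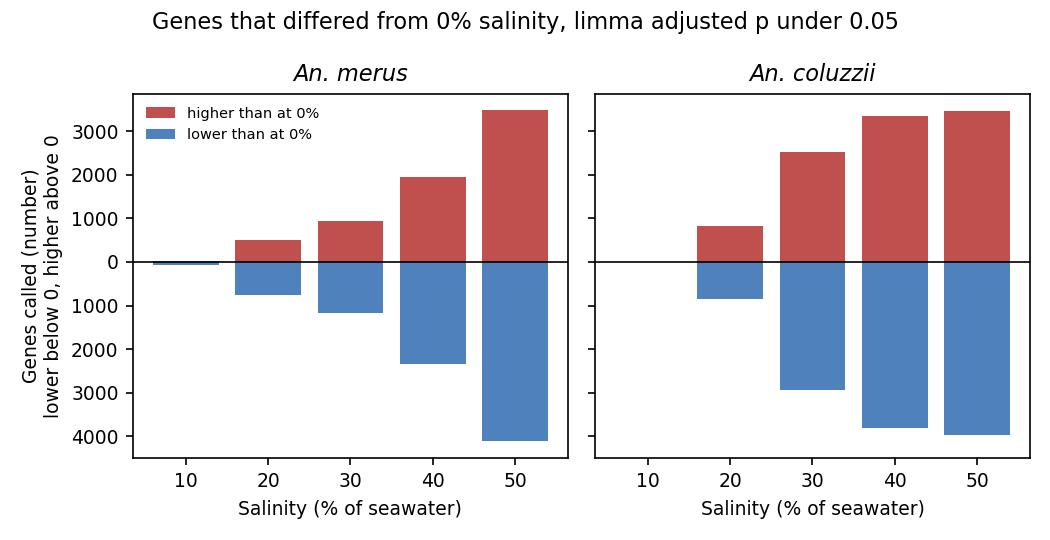
Number of genes higher (above 0) and lower (below 0) than at 0% salinity in each species, by salinity in percent of seawater, from limma at an adjusted p under 0.05 with 3 libraries per group. The count in An. merus reaches 7594 at 50%, and that in An. coluzzii is 5473 at 30% and 7417 at 50%.

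A linear trend over the 6 salinities was fitted in each species to find genes with a slope over salinity, which need not mean a graded course. In An. merus 7571 genes had a slope (3465 rising, 4106 falling; 2833 and 4581 with library totals as the scaling), and 4406 had one over 0 to 40% alone (1995 rising, 2411 falling); in An. coluzzii 8253 had a slope (3845 rising, 4408 falling; 2496 and 5990 with library totals as the scaling). AGAP009460 had nearly equal slopes in the species, 0.95 ± 0.05 log2 units per 10% of seawater in each (SE). Its course differed, however, since in An. coluzzii it measured 14.5 ± 2.07 CPM at 30%, 40.6 ± 13.6 CPM at 40% and 14.7 ± 2.73 CPM at 50% (SD, n = 3), and its change from 40 to 50% was 4.48 ± 0.31 in An. merus and -1.40 ± 0.31 in An. coluzzii on the log2 scale (SE). AGAP000239 rose in An. merus by 0.96 ± 0.14 log2 units per 10% (SE; limma adjusted p = 4.4e-07), and its slope in An. coluzzii was -0.22 ± 0.14 (SE; limma adjusted p = 0.14). AGAP004980 had a rising slope in An. coluzzii, 0.34 ± 0.06 log2 units per 10% (SE, limma adjusted p = 2.0e-05), although it was lower at 30% than at 0% (below).

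The species were compared at 0%, between larvae held in fresh water for the same 6 h as the others. AGAP010613 stood at 223 ± 52.3 CPM in An. merus and 0.263 ± 0.0383 CPM in An. coluzzii (SD, n = 3; log2 difference 8.17 ± 0.33 SE, limma adjusted p = 2.8e-18). AGAP001354 was also higher in An. merus, 87.3 ± 27.9 against 0.560 ± 0.211 CPM (SD, n = 3; log2 difference 6.35 ± 0.20 SE, limma adjusted p = 9.8e-21). AGAP007187 was lower in An. merus, 1.44 ± 0.686 against 534 ± 93.8 CPM (SD, n = 3; log2 difference -8.14 ± 0.22 SE, limma adjusted p = 4.5e-22), as was AGAP005598, 0.415 ± 0.329 against 149 ± 2.71 CPM (SD, n = 3; log2 difference -7.41 ± 0.20 SE, limma adjusted p = 2.4e-22). In all, 4741 genes differed (2399 higher and 2342 lower in An. merus), 1121 of them by at least 2-fold. Which direction was more frequent depended on the scaling and the model, with 1973 higher and 2653 lower with library totals, 2259 and 2468 with DESeq2, and 2737 and 2221 with quantile normalization. Among the 288 genes that differed by at least 4-fold, 194 were lower in An. merus (67.4%, exact 95% interval 61.6 to 72.7%). The interval takes genes as independent, which genes of the same libraries are not, so it is likely too narrow. No read was counted in any library of An. merus for 18 genes and of An. coluzzii for 3 genes. How well the reads of each species aligned was not measured here, so a difference in alignment cannot be separated from one in expression.

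Whether the species responded differently was tested with the interaction of species and salinity, in which a fold difference between the species that is the same at every salinity cancels, except near the floor, where the 0.5 CPM added to each value hides part of a change. AGAP009635 stood at 147 ± 55.3 CPM at 0% and 775 ± 57.1 CPM at 50% in An. merus, and at 441 ± 332 CPM at 0%, 1163 ± 219 CPM at 30% and 6.96 ± 0.587 CPM at 50% in An. coluzzii (SD, n = 3). Its response at 50% was higher in An. merus by 7.97 ± 0.67 on the log2 scale (SE; limma adjusted p = 1.5e-10). AGAP000239 rose in An. merus and fell in An. coluzzii at 50%, from 10.98 ± 10.9 to 1.43 ± 0.213 CPM after 52.7 ± 10.0 CPM at 30% (SD, n = 3). The fall in An. coluzzii was less certain (log2 fold change -1.99 ± 0.80 SE, limma adjusted p = 0.030). Its lowest library at 0% and its highest at 50% both measured 1.63 CPM. The difference in response between the species was 7.44 ± 1.13 (SE, limma adjusted p = 3.3e-06). AGAP004980 fell in An. merus from 29.0 ± 11.4 to 2.02 ± 1.75 CPM and rose in An. coluzzii from 14.7 ± 4.35 to 53.0 ± 2.32 CPM, with 0.747 ± 0.265 CPM at 30% (SD, n = 3; difference -5.54 ± 0.52 SE, limma adjusted p = 1.3e-09). AGAP010912 rose in An. coluzzii from 0.180 ± 0.0290 to 22.1 ± 4.25 CPM and measured 0.172 ± 0.0691 and 0.386 ± 0.275 CPM at 0 and 50% in An. merus (SD, n = 3; difference -4.68 ± 0.38 SE, limma adjusted p = 9.6e-11). The An. merus values of this gene rest on 7 and 18 reads in all, and edgeR, which adds no constant to the values it tests, called it as well (edgeR adjusted p = 0.00022).

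**Figure D3:**
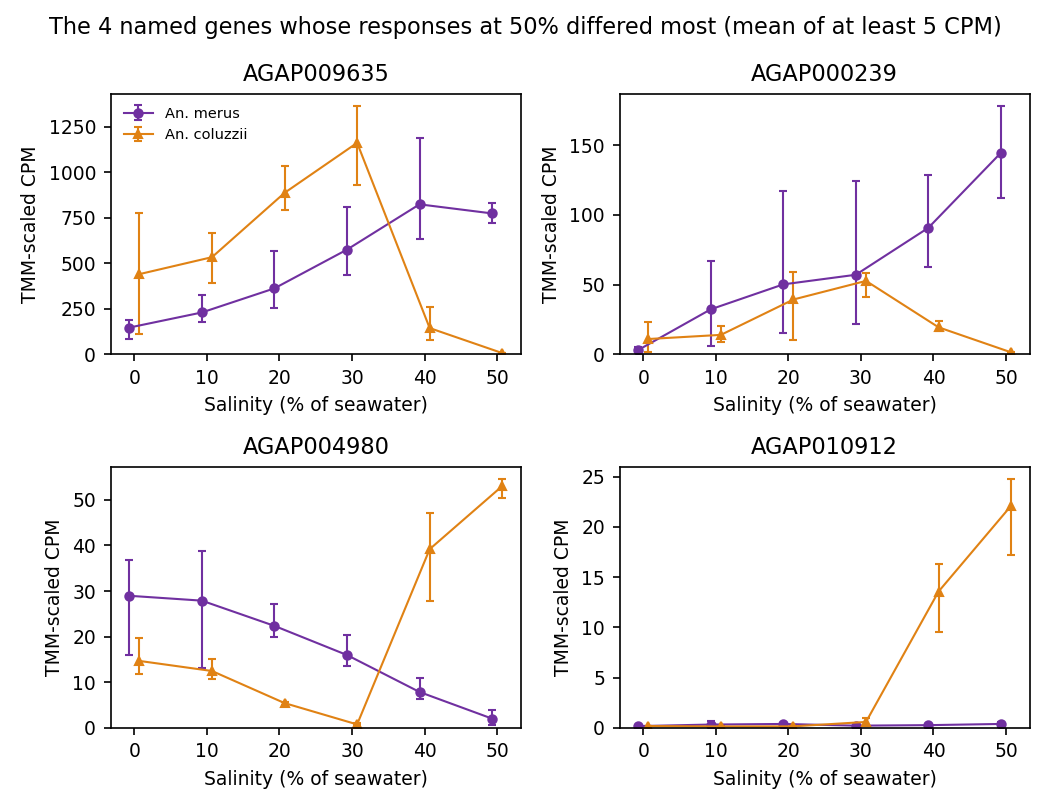
TMM-scaled CPM of 4 genes by salinity in percent of seawater, with markers for the mean and bars from the lowest to the highest of 3 libraries. AGAP009635 averages 775 CPM in An. merus and 6.96 CPM in An. coluzzii at 50%, after 1163 CPM in An. coluzzii at 30%.

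Over all salinities 7844 genes responded differently in the species (moderated F test, limma adjusted p under 0.05). At 50% the number was 5992, with the response higher in An. merus for 2792 and lower for 3200 (3243 and 2331 with library totals as the scaling), and 2580 differed by at least 2-fold. In 263 of the 5992 genes 1 species stayed under a mean of 1 CPM at 0 and 50% (174 in An. merus, 89 in An. coluzzii), and edgeR called 119 of these and not the other 144, a comparison added after the data were examined. The single tests at the lower salinities were added after the data were examined and gave 7 genes at 10%, 60 at 20% (20 higher, 40 lower), 2064 at 30% (1024 higher, 1040 lower) and 4823 at 40% (2497 higher, 2326 lower). With library totals as the scaling the higher and lower numbers were 5 and 5 at 10% (4 and 5 with quantile normalization, 6 and 7 with DESeq2), 27 and 29 at 20%, 1862 and 594 at 30% (1217 and 1008 with DESeq2), and 4145 and 1204 at 40%. That scaling moved the median difference of all genes by 0.10, 0.19, 0.31 and 0.15 log2 units at 20, 30, 40 and 50%. At 10% the response was higher in An. merus for 2 genes, AGAP001160 (log2 difference 0.97 ± 0.19 SE, limma adjusted p = 0.043) and AGAP005417 (0.87 ± 0.17 SE, limma adjusted p = 0.043). It was lower for 5, with the lowest values for AGAP002331 (-2.31 ± 0.30 SE, limma adjusted p = 0.00017) and AGAP005339 (-1.69 ± 0.31 SE, limma adjusted p = 0.028), all 4 chosen for naming after their values were seen. AGAP001160 and AGAP005417 lost their calls with a pseudocount of 2, under the replicate block and with edgeR, AGAP005417 also with quantile normalization, and AGAP005339 under the replicate block. Of 12 fits that each left out a library, AGAP001160 lost its call in 11, AGAP005417 in 8 and AGAP005339 in 7. Across the other alternatives the count at 10% ran from 1 under the replicate block to 13 with DESeq2. Leaving out a single library lowered the count at 10% to 1 (An. merus 10% B, An. coluzzii 10% B or C), to 3 (An. merus 0% A, An. merus 10% A, An. coluzzii 10% A) or to 4 (An. merus 0% B, An. merus 10% C, An. coluzzii 0% B or D). At 20% the count was 37 without An. merus 0% A, 100 without An. merus 0% B, 34 without An. merus 20% B, 30 without An. coluzzii 20% A and 32 without An. coluzzii 20% C.

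At 50% the species shared 4092 genes called in the same direction, 1898 risen and 2194 fallen. Independent lists of these lengths would share 1103 and 1494, and the excess was tested with a one-sided Fisher's exact test over genes, which are not independent replicates (p = 3.9e-262 risen, odds ratio 4.52; p = 2.2e-180 fallen, odds ratio 3.25). The comparisons use different control libraries. AGAP004581 and AGAP004583 are among the genes risen in both species and AGAP002798 among those fallen in both, with a fall by 6.18 ± 0.34 log2 units in An. coluzzii (SE). In 1163 genes the species went opposite ways, 638 risen in An. merus and fallen in An. coluzzii, such as AGAP009635, and 525 the other way, such as AGAP004980. Independent lists would give 1265 and 1302, so opposite calls were fewer than by chance. With library totals as the scaling, the shared genes divided into 1116 risen and 3241 fallen and the opposite ones into 803 and 270, and with quantile normalization into 2042 and 1871 and into 592 and 642, so neither division is settled.

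Log2 fold changes were correlated between the species across the 10905 genes, which are not independent replicates, for each of the 25 pairs of salinities. This comparison was added after the data were examined. At equal salinity Pearson's r was 0.24, 0.50, 0.48, 0.43 and 0.41 from 10 to 50%. The response of An. merus at 50% had an r of 0.77 (Spearman's rho 0.79) with that of An. coluzzii at 30%, 0.66 (0.69) at 40% and 0.41 (0.44) at 50%. The jackknife SE over libraries was 0.05 for the first and 0.09 for the last. Genes changed with the same sign in 81.9% of cases in the first pair and 67.4% in the last.

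**Figure D4:**
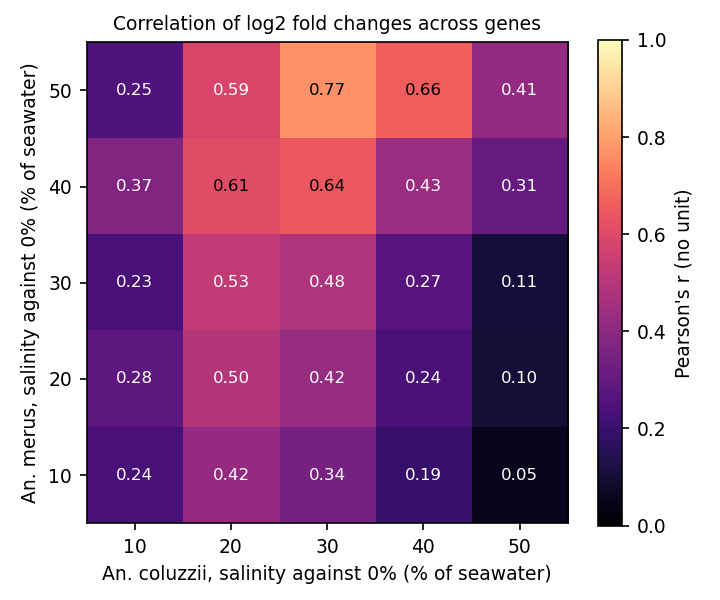
Pearson's r, across 10905 genes, of the log2 fold changes against 0% in An. merus (vertical axis, salinity in percent of seawater) and An. coluzzii (horizontal axis). The cell of An. merus at 50% and An. coluzzii at 30% has the highest r, 0.77, against 0.41 when both are at 50%.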

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

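The dose-shift test, the share of genes lower in An. merus, the permutation of residuals and the second set of splits were chosen only after the results they bear on had been seen. Results stand here because the response to the same salinity differed between the species by a test of the difference itself.

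The F test found 7844 genes with different responses, and 5992 differed at 50%. Equal responses in both species were tested by keeping the additive effects of species and salinity and permuting the residuals over the libraries. For noise around equal responses, 1 of 100 draws, the real one, gave as many genes in the F test (highest other 23). At single salinities the draws as large, the real one included, were 5 of 100 for the 7 genes at 10% (highest other 259), 3 for the 60 genes at 20% (highest other 173), 1 for the 2064 genes at 30% (highest other 1327), 1 for the 4823 genes at 40% (highest other 2319) and 2 for the 5992 genes at 50% (highest other 6051). In the F test and at 30 and 40% no other draw reached the real count, which argues against chance there. At 10, 20 and 50% at least 1 other draw exceeded it. The median of the other draws was 0 genes in the F test and at every salinity. The permuted residuals still hold any real difference in response, so a high draw need not be noise alone. With 5 salinities tested and the test chosen afterwards, the draws do not exclude chance at these 3, nor do they show it. The permutation takes libraries of all groups to vary alike, while those at 0% stood further apart (below), so all these shares are approximate.

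Splits that relabel salinity within each species, planned as the test of chance, remove or turn the responses and do not make them equal, so they decide nothing about the interaction, and a second set of such splits has the same limit. The real count or more came in 8 of 100 splits at 10% (highest other 92), 21 at 20% (highest other 3106), 8 at 30% (highest other 5723), 9 at 40% (highest other 7298), 2 at 50% (highest other 6323) and 1 for the F test (highest other 1817). From 10 to 40% the highest counts are those of all labels of 1 species exchanged, which tests the sum of the responses.

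The species went opposite ways in 1163 genes at 50% (1 of 100 splits, highest other 1) and shared 4092 (1 of 100, highest other 7). The other splits mix the 0 and 50% libraries and so remove the responses themselves, so they decide nothing about how the responses of the species relate. The 638 and 525 opposite genes were fewer than the 1265 and 1302 that independent lists would give. The named genes with differences in response were AGAP009635 (log2 difference 7.97), AGAP000239 (7.44), AGAP004980 (-5.54) and AGAP010912 (-4.68).

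The response of An. merus at 50% resembled that of An. coluzzii at 30% more than that at 50%, by 0.357 in r. The tables argue against unequal depth (a difference of 0.350 with every library thinned to 9174563 reads), against noise in low genes (0.444 among the 2917 genes with a mean of at least 50 CPM) and against a single library (0.317 at the smallest, without An. coluzzii 0% D). A biological candidate explanation is a shift in dose, with An. merus reaching at 50% what An. coluzzii reaches at 30%. As a full equality it is argued against, since 22.5% of genes (2459) differed between those responses, and 14.1 (without An. merus 0% A) to 28.6% with each of 12 libraries left out. A partial shift stays open as a hypothesis. The response of An. merus at 30 and 40% also had its highest r at a lower salinity of An. coluzzii (0.53 with 20%, 0.64 with 30%). At 20% its highest r was at equal salinity (0.50), and at 10% at a higher one (0.42 with 20%). Few genes were called at 10%, 87 in An. merus and 6 in An. coluzzii.

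Among genes that differed at least 4-fold between the species at 0%, 67.4% were lower in An. merus. The share lower was 47.1% under 2-fold, 53.3% at 2 to 4-fold, 68.8% at 4 to 16-fold (exact 95% interval 62.7 to 74.5%) and 57.9% above 16-fold (40.8 to 73.7%). These intervals, too, take genes as independent. Loss of merus reads in alignment or counting would lower genes in An. merus, but the share is the observation itself and tests no cause, and no alignment rates or genome were used here, so read loss and a difference in expression both stay open.

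The libraries at 0% stood furthest from the others of their own group, 5 of the 6 with the greatest root mean square distance, which averaged 0.437 log2 units in An. merus and 0.404 in An. coluzzii against 0.233 to 0.327 in the other 10 groups. Lower depth is argued against, since 5 of the 6 were again libraries at 0% after thinning to 9174563 reads. Differences between the pools in handling or in development stay open and were not tested.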

How the results depend on the processing

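The scaling by library totals, the alternatives for genes named at 10%, and all results for the interaction at 10 to 40%, the opposite calls, the correlations and the change from 40 to 50%, were chosen only after the data were seen. Of 225 counts under alternatives other than leaving out a library, 214 stayed within 1.5 times the reported count. None of 155 values of genes named by rule lost its direction or its call, and none of 20 correlations changed sign. The rule took the largest changes among called genes of the same libraries, so little else could come out for these genes. The 7 genes named at 10% kept their call in 53 of 65 values, and in 33 of 66 with a library left out; only AGAP006968 and AGAP002331 kept it in all. Exceptions among the counts were An. merus at 10%, 87 genes, with 52 when each species was fitted alone and 141 with DESeq2; An. coluzzii at 10%, 6 genes, with 2 under the replicate block, 1 fitted alone and 17 with DESeq2; An. merus at 20%, 1283 genes, with 557 fitted alone; and the interaction at 10%, 7 genes, with 4 at a pseudocount of 2, 1 under the block and 13 with DESeq2. The An. merus trend fell from 7571 to 4406 with the slope over 0 to 40%, which leaves out the 50% libraries, and the species difference rose from 4741 to 8351 averaged over 6 salinities, which uses 36 libraries. The cause of the other changes was not tested. Residuals of same-letter libraries correlated at 0.10 on average in An. merus (23 of 45 pairs over 0.1) and 0.09 in An. coluzzii (16 of 36), against -0.05 (24 of 90) and -0.03 (30 of 99) for different letters, and 18 of 36 libraries correlated best with their own letter, against 10.5 if each letter had the same chance. The values lean towards a letter effect. The tests planned in advance had no block, so the libraries were left unpaired and the block was run as an alternative. The counts at 10% in An. coluzzii and for the interaction depend on this choice (above). The block gave 7710 and 7218 genes at 50% in An. merus and An. coluzzii.

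With each library left out, 200 of 234 counts stayed within 1.5 times. The ranges beyond it were 32 to 415 for An. merus at 10%, 270 to 2193 at 20% and 874 to 2865 at 30%; 1 to 9 for An. coluzzii at 10% and 551 to 2020 at 20%; and 1 to 8 and 30 to 100 for the interaction at 10 and 20%. All 120 values of the genes named by rule kept direction and call, with the same limit, and all 24 correlations kept their sign. The gene lists were not run, for want of names, and DESeq2 was not run for the F test, as planned.

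Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real count and the highest other were 87 and 628 for An. merus at 10% (2 of 10 as large), 1283 and 650 at 20%, 2112 and 1 at 30%, 4286 and 852 at 40%, and 7594 and 1 at 50%. In An. coluzzii they were 6 and 4, 1673 and 7, 5473 and 218, 7154 and 80, and 7417 and 15, for the species at 0% 4741 and 1152, and from 40 to 50% 4886 and 1 in An. merus and 4723 and 1 in An. coluzzii (1 of 10 each). The split with 628 set An. merus 0% A and C with 10% C. For the trends no other relabelling of single libraries reached the real count (1 of 100 each, the real one included, highest others 5981 and 5588). This argues against chance if the pools are independent. The labels do not say whether pools of a group came from separate cultures, and differences between cultures were not tested.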

Other observations

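The comparison of 50 with 40% and its relation to the response at 30% were chosen after the main results had been seen. From 40 to 50% 4886 genes changed in An. merus (2116 risen, 2770 fallen; 1090 and 3755 with library totals as the scaling, which moved the median by -0.15 log2 units) and 4723 in An. coluzzii (2351 risen, 2372 fallen; 2664 and 2196 with quantile normalization). AGAP009635 fell by 4.07 ± 0.47 log2 units in An. coluzzii over this step (SE; limma adjusted p = 1.0e-07). It had risen by 1.77 ± 0.47 from 0 to 30% (SE; limma adjusted p = 0.0026) and was already lower at 40% than at 0% by 1.43 ± 0.47 (SE; limma adjusted p = 0.0094), so its turn came before this step. AGAP004980 fell by 3.59 ± 0.37 in An. coluzzii from 0 to 30% (SE; limma adjusted p = 9.0e-09) and was higher at 40% than at 0% by 1.39 ± 0.37 (SE; limma adjusted p = 0.0017), so its turn too came before the last step, over which it changed by 0.46 ± 0.37 (SE; limma adjusted p = 0.32). In An. merus it fell by 1.92 ± 0.37 from 40 to 50% (SE; limma adjusted p = 0.00013).

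Turns such as these raised the hypothesis that the last step of salinity may undo in An. coluzzii what lower salinity had done, although in both genes the turn came earlier. The change from 40 to 50% was set against that from 0 to 30%, which share no library. Across genes r was -0.349 in An. coluzzii (-0.455 to -0.246 with each of 12 libraries left out) and 0.306 in An. merus (0.213 to 0.345). Of the 2526 genes risen at 30% in An. coluzzii, 1171 fell from 40 to 50%, against 549 for independent lists, and of the 2947 fallen, 1221 rose, against 635. In An. merus 52 of 948 and 105 of 1164 genes reversed in that way, against 241 and 226. The values went with the hypothesis in An. coluzzii and against it in An. merus. The hypothesis arose from these same libraries, and the step from 30 to 40% was not examined. The values therefore do not place the start of the reversal in the last step. Whether damage, developmental delay or regulation lies behind the reversal was not tested.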
